A study of Mus musculus with 45 samples.

How the data were processed

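Left ventricular tissue of wild-type mice was sampled at 4, 6 and 8 weeks of age after a sham operation, a constriction of the aorta (nAAC) or a reversible constriction (Rev-nAAC) done within a day of birth. Each of the 9 groups held 5 libraries of total RNA, 45 in all. Per the labels, the authors extracted RNA with Trizol, made libraries with a VAHTS Universal V6 kit and used fastp 0.20.1, HISAT2 2.1.0 and HTSeq 0.11.2 with the mouse build GRCm38, also called mm10. The deposited values are counts of reads per gene with no normalization. The values were checked to be whole numbers, with totals that differ between libraries. The gene annotation, the strand setting and the counting of shared reads are not stated, so values of genes with overlapping or close copies, such as the globins, the H2 genes, Lilrb4a and Lilrb4b, are uncertain.

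Of 27007 genes in the table, 25521 were matched by symbol to the RefSeq annotation of GRCm38.p6, which gave the coordinates. The 13 mitochondrially encoded proteins were matched through their mitochondrial names. No gene was 0 in all libraries, and 0 columns of values per sample were left unused. Library totals of 31.6 to 36.0 M counts (M, mega) set the precision of low counts, and a count of 0 in 1 library covers counting error only. No library was a copy of another, since the closest pair, sham 4-week replicates 4 and 5, had a correlation of 0.990. Library nAAC 4-week replicate 1 was grouped by its title, against its treatment tag. Sex was read from Xist and 4 Y-linked genes. Red cell, adipocyte and mitochondrial shares were measured in each library.

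The fit used edgeR 4.0.16 in R 4.3.3, with TMM normalization and filterByExpr (minimum count 10, minimum total 15), which left 15444 genes. Dispersions were estimated with the robust option over all 45 libraries and the 9 groups. Quasi-likelihood tests compared nAAC with sham, Rev-nAAC with nAAC and Rev-nAAC with sham at each age, sham at 8 with sham at 4 weeks, and these effects at 8 with those at 4 weeks. P-values were adjusted by Benjamini-Hochberg within a comparison, at a threshold of 0.05. CPM are counts scaled to a common library size, computed with the TMM library sizes. Replicate numbers were checked for pairs, and in the 9 comparisons at most 2 of the same-numbered pairs passed a correlation of 0.1, so the fit held no block.

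For each of the 9 comparisons of operations, 41 gene lists of pathways, cell types and cardiac programs were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and a prior count of 2, adjusted over the 41 lists. Each test was repeated with the correlation estimated from the libraries and with fry, which compares a list with no other genes. With an estimated correlation only the stress program list passed, in nAAC against sham at 4 weeks and in Rev-nAAC against nAAC at 6 weeks. Every list past the threshold had a median, a mean and a test of 1 sign, while these differed in sign in 40 other list results. Counts of members are given over all genes tested and adjusted over the list alone. Some members belong to more than 1 list.

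The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. In each comparison the rule named the 8 largest rises and 8 largest falls among genes past the threshold that had at least 2 CPM in the higher group and did not overlap between groups, passing over predicted and unnamed gene models. It also named a panel of 16 load-response genes and up to 4 members of each list with the smallest p. Sham ages and interactions took the 5 largest in each direction and the panel. Some genes the rule named are not reported here.

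Genes were called with 3 nAAC and 3 sham libraries, over 20 splits with a fixed seed. Median signed differences from the other 2 sham libraries were taken in Rev-nAAC and the other 2 nAAC libraries. The recovered share is the part of the nAAC median missing from Rev-nAAC. Ages were compared by two-sided exact permutation tests over the 5 values per Rev-nAAC group, which share the nAAC and sham libraries of their age. The position of a library is its projection on the line from the sham mean to the nAAC mean of its age, computed without that library. For overlaps, 10 data sets per age were simulated with no difference between any groups, and overlaps were also counted with separate libraries on both sides.

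Alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE normalization, no filter, only the compared groups in the fit, a replicate block, sex as a covariate, each library left out in turn, and nAAC 4-week replicate 1 counted as sham. The stricter threshold for the recovered share was 0.01. After the data were seen, fits of the male libraries alone, fits without 4 doubted libraries and a recovered share with the sex term removed were added. The doubted libraries were nAAC 4-week replicate 1 (labels), nAAC 4-week replicate 5 (low correlation with its group), Rev-nAAC 4-week replicate 2 (red cells) and Rev-nAAC 8-week replicate 4 (fat cells). Each count was compared with 100 of the 126 splits of its 10 libraries, and each interaction with 100 of 31752 ways to permute the 2 ages within both operations.

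The method was tested on simulated data with 200 changed genes among 15204. In nAAC against sham at 8 weeks it recovered 32 of 49 genes changed 1.5-fold, 36 of 49 changed 2-fold, 48 of 49 changed 4-fold and 50 of 50 changed 8-fold, with 7 unchanged genes called. For the interaction it recovered 15, 31, 43 and 47 of these, with 7 unchanged genes called. A comparison with no change gave 0 genes, a lowered list had adjusted p = 1.3e-22, and a simulated share of 60% was measured as 59.8%.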

Results

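RNA was sequenced from left ventricular tissue of wild-type mice that had been operated on within a day of birth. The pups had a sham operation, an aortic constriction (nAAC) or a reversible aortic constriction (Rev-nAAC). Hearts were taken at 4, 6 and 8 weeks of age, with 5 libraries in each of the 9 groups and 45 libraries in all. The labels do not state when the reversible constriction was released. Each value was the number of reads counted for a gene, and library totals ranged from 31.6 to 36.0 M counts (M, mega). Sham totals lay between 33.2 and 33.8 M at 4 weeks, 32.3 and 34.1 M at 6 weeks, and 34.5 and 35.2 M at 8 weeks. In nAAC they ran from 33.1 to 34.4, from 31.6 to 36.0 and from 34.4 to 35.5 M at these ages, and in Rev-nAAC from 33.2 to 35.2, from 32.6 to 34.2 and from 33.5 to 34.8 M. The table held 27007 genes, and 15444 had enough counts to be tested. P-values measure the spread between libraries, since the labels do not say outright that each library came from a separate animal.

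Transcripts of the mitochondrial genome took 29.3 ± 1.08% of counts in sham hearts at 4 weeks (SD, n = 5), 30.3 ± 1.77% at 6 weeks and 25.8 ± 1.15% at 8 weeks. Their share was lower in nAAC hearts, at 24.6 ± 2.42%, 23.0 ± 3.27% and 21.5 ± 1.45%, and in Rev-nAAC hearts it was 23.9 ± 1.64%, 25.8 ± 1.70% and 24.7 ± 1.21%. COX1, a mitochondrial subunit of cytochrome c oxidase, had the most counts summed over the 45 libraries. Xist and 4 Y-linked genes showed that all 15 sham libraries were male, whereas females numbered 3, 4 and 2 of 5 in nAAC and 2, 2 and 4 of 5 in Rev-nAAC at 4, 6 and 8 weeks. One library, nAAC 4-week replicate 1, carries a treatment tag that says sham although its title says nAAC, and it was kept with nAAC. Globin and other red cell transcripts reached 1.17% of counts in Rev-nAAC 4-week replicate 2. Marker genes of fat cells were high in Rev-nAAC 8-week replicate 4 and in sham 4-week replicate 1. Library nAAC 4-week replicate 5 had the lowest median correlation with its own group, at 0.967. Rev-nAAC 6-week replicate 4 lay close to the sham hearts, as the positions between sham and nAAC show.

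**Figure D1:**
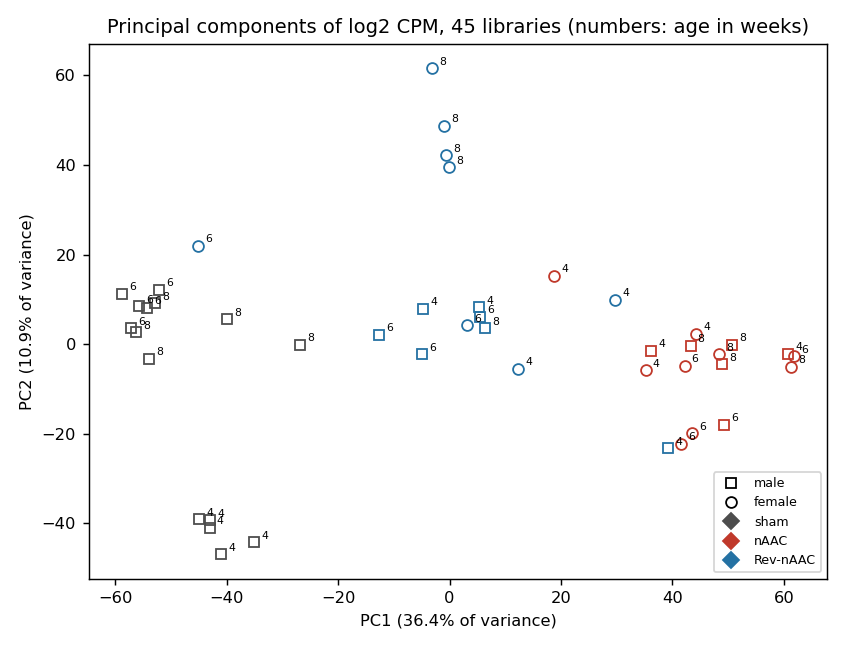
Points are the 45 libraries on the leading components of log2 CPM, with 36.4% (horizontal) and 10.9% (vertical) of the variance. Colour gives the operation, shape the sex and the number the age in weeks. At 4, 6 and 8 weeks sham averages -41.4, -55.6 and -46.0 horizontally and nAAC 39.0, 47.6 and 50.5. Vertically sham averages -42.1, 8.70 and 2.78 and 4-week nAAC 1.63.

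The comparison of nAAC with sham asks how the ventricle responded to lasting pressure load begun at birth. At 4 weeks the natriuretic peptide gene Nppa averaged 9559.5 ± 4147 CPM in nAAC hearts and 85.2 ± 25.7 in sham hearts (SD, n = 5), a log2 fold change of 6.81 ± 0.56 (SE). Beta-myosin heavy chain, Myh7, rose from 63.9 ± 5.01 to 4513 ± 1403 CPM. The adult isoform Myh6 fell by 0.62 on the log2 scale and the calcium pump gene Atp2a2 by 0.76. Skeletal actin and signals of stretch and scarring rose, with Acta1 (3.43 ± 0.50), Ankrd1 (3.13 ± 0.35), Nppb (2.46 ± 0.39), Ccn2 (3.60 ± 0.41), Postn (3.03 ± 0.49), Tgfb2 (2.41 ± 0.26) and Timp1 (2.70 ± 0.47) (largest adjusted p = 1.8e-05, Timp1). The largest rises included those of the tendon gene Tnmd and the keratin gene Krt8, with Sprr1a (7.36 ± 0.98), Tnmd (6.80 ± 0.99), Krt8 (6.75 ± 0.64) and Chil1 (6.39 ± 1.17). Vgll2 and Chodl were almost absent from sham hearts, at 0.00609 ± 0.0136 and 0.0380 ± 0.0519 CPM, and reached 9.33 ± 3.71 and 3.94 ± 2.14 CPM in nAAC. The water channel gene Aqp4 fell most, from 13.4 ± 0.841 to 0.0412 ± 0.0465 CPM, followed by Mme (-4.20 ± 0.42), Col6a6 (-4.06 ± 0.49), Rgs7 (-3.93 ± 0.51), Plekhh1 (-3.82 ± 0.35), Lypd8l (-3.64 ± 0.47), Efemp1 (-3.63 ± 0.59) and Pla2g5 (-3.58 ± 0.40). In the genome build GRCm38.p6, Nppa on chromosome 4 from 148000722 to 148002074, Myh7 on chromosome 14 from 54970684 to 54994626, Ccn2 on chromosome 10 from 24595442 to 24598683 and Aqp4 on chromosome 18 from 15389394 to 15410982 are protein-coding genes. In all, 6283 genes passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 3016 higher and 3267 lower, of which 955 and 890 changed at least 2-fold. Panel genes that did not pass were Cpt1b (-0.16), Ppargc1a (-0.34), Col3a1 (-0.50) and Fn1 (0.44). Col1a1 rose by 0.71 ± 0.28 (adjusted p = 0.036), a call that ended without sham replicates 2, 3, 4 or 5 or nAAC replicates 2, 3 or 4 (adjusted p from 0.056 to 0.13). With nAAC replicate 1 counted as sham, Myh7 had a log2 value of 2.06 and adjusted p = 0.065.

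Of the 24 stress program genes, 22 rose and 0 fell (the same adjusted over the list alone), upward with adjusted p = 9.4e-20, or adjusted p = 0.030 with an estimated correlation. Of the 45 extracellular matrix genes, 25 rose and 2 fell (26 and 2 adjusted over the list alone), upward with adjusted p = 3.4e-06, or adjusted p = 0.54 with an estimated correlation. Of the 36 cell cycle genes, 0 rose and 32 fell (0 and 33 adjusted over the list alone), downward with adjusted p = 2.1e-09, or adjusted p = 0.41 with an estimated correlation. Mitotic genes such as Cenpe (-2.35 ± 0.38), Cenpf (-2.62 ± 0.42), Kif11 (-2.17 ± 0.38) and Anln (-1.87 ± 0.32) were lower in nAAC. Of the 33 fatty acid oxidation genes, 0 rose and 18 fell (0 and 19 adjusted over the list alone), downward with adjusted p = 3.9e-05, or adjusted p = 0.54 with an estimated correlation. Of the 54 oxidative phosphorylation genes, 0 rose and 37 fell (0 and 40 adjusted over the list alone), downward with adjusted p = 4.6e-09, or adjusted p = 0.54 with an estimated correlation. Examples were Acaa2 (-1.26 ± 0.18), Ndufs1 (-0.56 ± 0.10) and Sdha (-0.58 ± 0.11), in libraries with a lower share of mitochondrial transcripts. Of the 23 immediate early genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone), upward with adjusted p = 5.0e-05, or adjusted p = 0.44 with an estimated correlation. Of the 22 oxidative stress genes, 15 rose and 2 fell (the same adjusted over the list alone), upward with adjusted p = 2.9e-04, or adjusted p = 0.41 with an estimated correlation. The NADPH oxidase Nox4 was among the latter, at 4.21 ± 0.46. Of the 22 macrophage marker genes, 4 rose and 10 fell (the same adjusted over the list alone), downward with adjusted p = 0.043, or adjusted p = 0.66 with an estimated correlation. Its members moved apart, with Csf1r (-1.0 ± 0.16), Cx3cr1 (-1.68 ± 0.32) and Cd163 (-1.30 ± 0.24) lower and osteopontin, Spp1 (4.23 ± 0.75), higher. The macrophage call ended without sham replicate 1 (adjusted p = 0.097) or nAAC replicate 1 (adjusted p = 0.19), with sex as a covariate (adjusted p = 0.087) and without the 4 doubted libraries (adjusted p = 0.12). With nAAC replicate 1 as sham the list stood at -0.19 (adjusted p = 0.59).

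**Figure D2:**
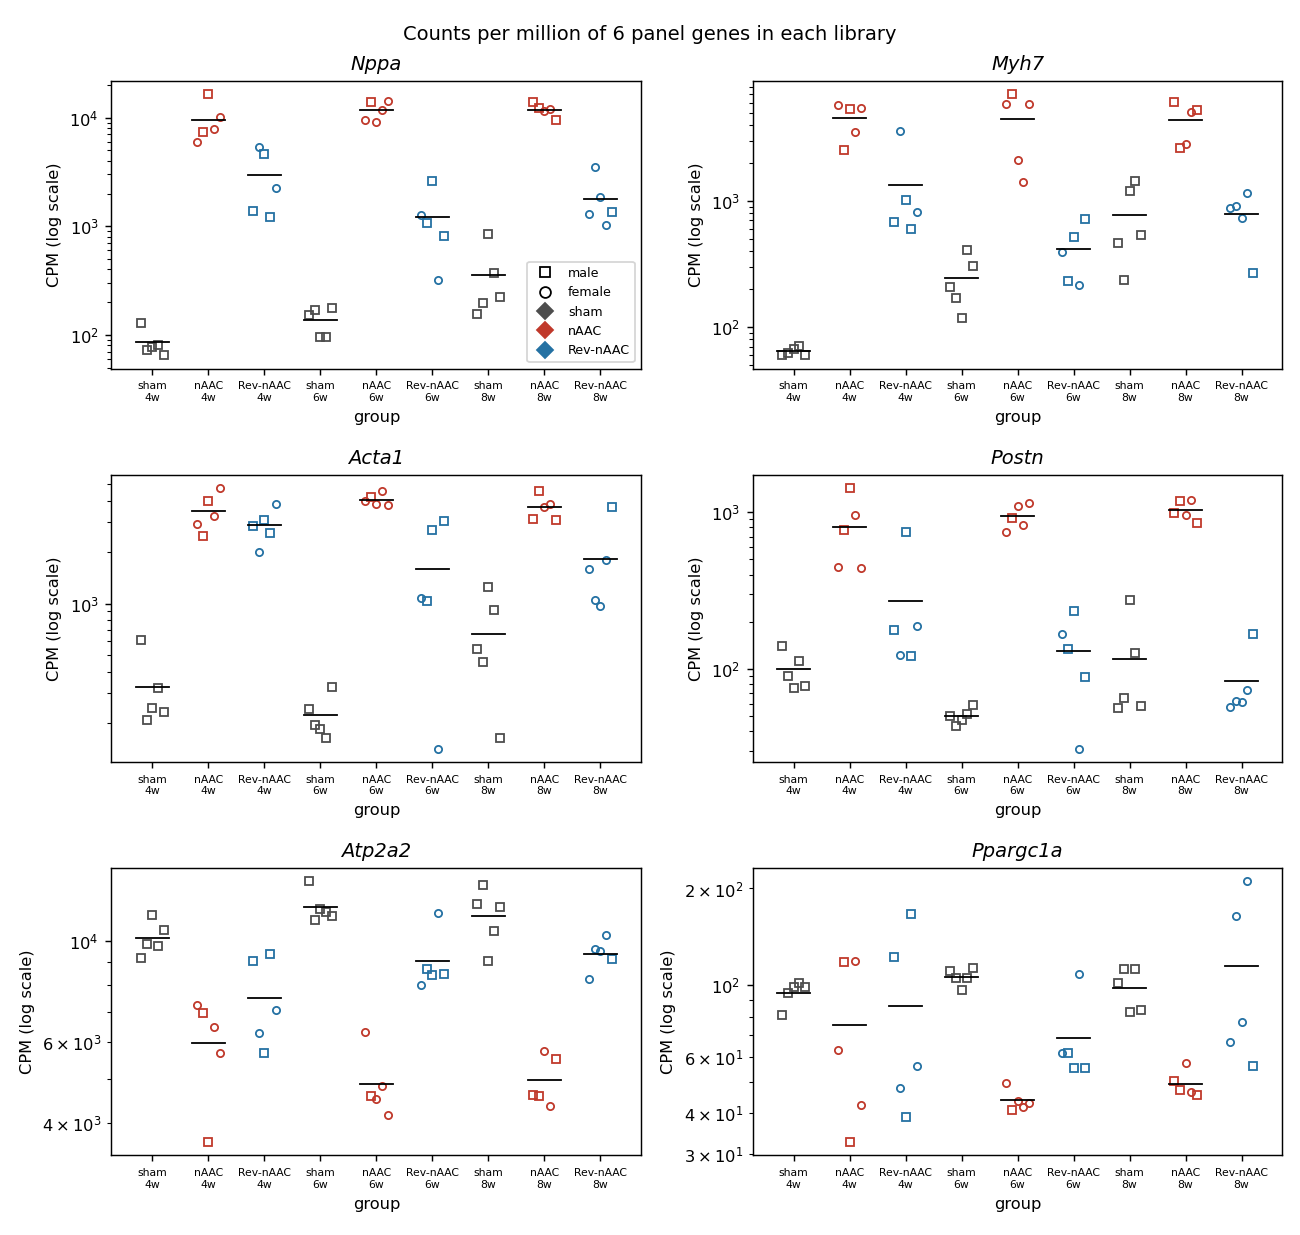
CPM of 6 genes in each library on logarithmic axes, by group, with black lines at the group means, colour for the operation and shape for the sex. Nppa averages 85.2, 137 and 357 CPM in the sham groups and 9559.5, 11726 and 11800.0 CPM in the nAAC groups, with Rev-nAAC in between.

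At 6 weeks nAAC hearts held far more natriuretic peptide and scar matrix transcripts than sham hearts. Nppa averaged 11726 ± 2319 CPM against 137 ± 39.0, periostin, Postn, 945 ± 173 against 50.1 ± 5.57, and Acta1 4076 ± 311 against 222 ± 64.0 (SD, n = 5). Collagens and fibronectin rose, with Col1a1 (1.78 ± 0.28), Col3a1 (1.63 ± 0.30) and Fn1 (1.67 ± 0.24), as did Nppb (2.91 ± 0.40), Myh7 (4.20 ± 0.55), Ankrd1 (2.75 ± 0.35), Tgfb2 (2.45 ± 0.26), Ccn2 (3.79 ± 0.41) and Timp1 (2.74 ± 0.47). Falls took in Myh6 (-1.14 ± 0.17), Atp2a2 (-1.28 ± 0.14) and Ppargc1a (-1.28 ± 0.34), the last a regulator of mitochondrial genes (largest adjusted p = 0.0018, Ppargc1a). The test was not passed by Cpt1b (-0.02). The largest rises included those of Sprr1a (6.88 ± 0.93), Vgll2 (6.83 ± 0.78), Serpinb1c (6.48 ± 0.67), Lrp8 (6.44 ± 0.52) and Tnmd (6.39 ± 1.01), besides Chodl, which went from 0.0134 ± 0.0184 to 2.62 ± 1.98 CPM. The largest falls included Acsm5 (-5.72 ± 0.60), Penk (-5.49 ± 0.87), Aqp4 (-5.42 ± 0.54), Clcn1 (-5.32 ± 0.64), Efemp1 (-4.92 ± 0.64), Uckl1os (-4.53 ± 0.50) and Cyp1a1 (-4.45 ± 0.80). The X-linked Xist averaged 344 ± 204 CPM in nAAC, with 4 female libraries, against 0.0344 ± 0.0349 in the male sham group, and did not pass in limma voom with quality weights (adjusted p = 0.45). The count was 7453 genes, 3779 higher and 3674 lower, with 1498 and 905 of them at least 2-fold, and 4500 in the male libraries, which leave 1 nAAC heart.

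Stress program genes, 24 in number, had 22 rises and 0 falls (the same adjusted over the list alone), upward with adjusted p = 6.5e-18, or adjusted p = 0.054 with an estimated correlation. Extracellular matrix genes, 45 in number, had 43 rises and 1 fall (the same adjusted over the list alone), upward with adjusted p = 9.4e-19, or adjusted p = 0.20 with an estimated correlation. Interferon response genes, 25 in number, had 25 rises and 0 falls (the same adjusted over the list alone), upward with adjusted p = 1.4e-08, or adjusted p = 0.32 with an estimated correlation. The antiviral genes Ifit2 (1.36 ± 0.18), Usp18 (1.77 ± 0.24) and Oasl2 (1.43 ± 0.24) were among them. Antigen presentation genes, 15 in number, had 11 rises and 0 falls (the same adjusted over the list alone), upward with adjusted p = 7.8e-04, or adjusted p = 0.43 with an estimated correlation. Class I components led, with B2m (1.40 ± 0.20), H2-D1 (1.08 ± 0.17) and Tap1 (1.08 ± 0.23), although H2 genes have close copies and uncertain values. Cell cycle genes, 36 in number, had 33 rises and 1 fall (the same adjusted over the list alone), upward with adjusted p = 5.1e-12, or adjusted p = 0.23 with an estimated correlation. Cyclin B1 and the ubiquitin conjugase of mitosis rose, with Ccnb1 (5.31 ± 0.80) and Ube2c (3.81 ± 0.51), and Cenpf (-3.51 ± 0.44) fell. Fatty acid oxidation genes, 33 in number, had 2 rises and 29 falls (the same adjusted over the list alone), downward with adjusted p = 1.2e-14, or adjusted p = 0.23 with an estimated correlation. Beta-oxidation enzymes such as Decr1 (-1.58 ± 0.13), Hadhb (-1.23 ± 0.10) and Etfa (-1.11 ± 0.09) were lower. Potassium and sodium channel genes, 24 in number, had 2 rises and 18 falls (the same adjusted over the list alone), downward with adjusted p = 2.6e-07, or adjusted p = 0.20 with an estimated correlation. These included the repolarizing channels Kcnd2 (-2.58 ± 0.28), Kcnd3 (-1.63 ± 0.18) and Kcnj3 (-3.51 ± 0.37).

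By 8 weeks nAAC hearts held 11800.0 ± 1635 CPM of Nppa against 357 ± 282 in sham (SD, n = 5), and the stress cytokine Gdf15 rose from 0.484 ± 0.201 to 39.9 ± 17.3 CPM. Keratins Krt8 (5.61 ± 0.54) and Krt18 (5.63 ± 0.57) and the cartilage collagen Col9a2 (5.74 ± 0.55) were among the largest rises, with Vgll2 (7.66 ± 0.74), Chodl (6.75 ± 0.98), Sprr1a (5.40 ± 0.75) and Tnmd (5.37 ± 0.88). Panel genes that rose were Nppb (2.91 ± 0.40), Myh7 (2.50 ± 0.51), Acta1 (2.46 ± 0.48), Ankrd1 (2.91 ± 0.35), Postn (3.15 ± 0.50), Tgfb2 (2.87 ± 0.26), Ccn2 (3.46 ± 0.40), Col1a1 (1.18 ± 0.28), Col3a1 (1.03 ± 0.30), Fn1 (1.22 ± 0.24) and Timp1 (1.07 ± 0.43). Falls were seen in Myh6 (-1.17 ± 0.17), Atp2a2 (-1.19 ± 0.14) and Ppargc1a (-0.99 ± 0.33) (largest adjusted p = 0.036, Timp1). No call was made for Cpt1b (-0.64). Aqp4 fell from 7.60 ± 2.31 to 0.0484 ± 0.0451 CPM, beside Clcn1 (-6.09 ± 0.71), Efemp1 (-5.41 ± 0.65), Uckl1os (-5.14 ± 0.51), Col6a6 (-4.93 ± 0.55), Acsm5 (-4.83 ± 0.57) and Cyp26b1 (-4.60 ± 1.20). At this age 7294 genes passed, 3668 higher and 3626 lower, with 1256 and 905 at least 2-fold. Across the 3 ages 3246 genes differed from sham in the same direction, 1612 higher and 1634 lower, against 358 if the ages were independent. The Timp1 call ended without sham replicates 1, 2 or 5 or nAAC replicates 1, 2 or 4 (adjusted p from 0.054 to 0.14). Sham replicate 3 held 840 CPM of Nppa and the other 4 held 155 to 372, and without it the log2 value of Nppa was 5.64 in place of 5.05.

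The extracellular matrix list held 40 rises and 3 falls among 45 genes (the same adjusted over the list alone), upward with adjusted p = 5.8e-14, or adjusted p = 0.27 with an estimated correlation. The activated fibroblast list held 12 rises and 3 falls among 16 genes (13 and 3 adjusted over the list alone), upward with adjusted p = 1.1e-05, or adjusted p = 0.27 with an estimated correlation. The interferon response list held 21 rises and 0 falls among 25 genes (22 and 0 adjusted over the list alone), upward with adjusted p = 4.2e-06, or adjusted p = 0.45 with an estimated correlation. The lymphocyte marker list held 5 rises and 0 falls among 13 genes (the same adjusted over the list alone), upward with adjusted p = 0.020, or adjusted p = 0.49 with an estimated correlation. B cell genes such as Ms4a1 (2.82 ± 0.79) and Cd79a (2.72 ± 0.72) were higher, and the list call ended with sex as a covariate (adjusted p = 0.059). Most listed genes that come up after birth fell. The adult-side maturation list held 2 rises and 17 falls among 25 genes (2 and 18 adjusted over the list alone), downward with adjusted p = 5.4e-07, or adjusted p = 0.27 with an estimated correlation. Insulin-responsive glucose transport and mitochondrial regulation were represented by Slc2a4 (-1.18 ± 0.11) and Esrra (-0.85 ± 0.09). The unfolded protein response list held 12 rises and 1 fall among 24 genes (the same adjusted over the list alone), upward with adjusted p = 0.020, or adjusted p = 0.61 with an estimated correlation. The cell cycle list held 13 rises and 3 falls among 36 genes (12 and 2 adjusted over the list alone), not past the threshold with adjusted p = 0.095. Here Hmmr (2.38 ± 0.67) and Tyms (0.69 ± 0.20) rose and Cenpf (-3.36 ± 0.45) fell.

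**Figure D3:**
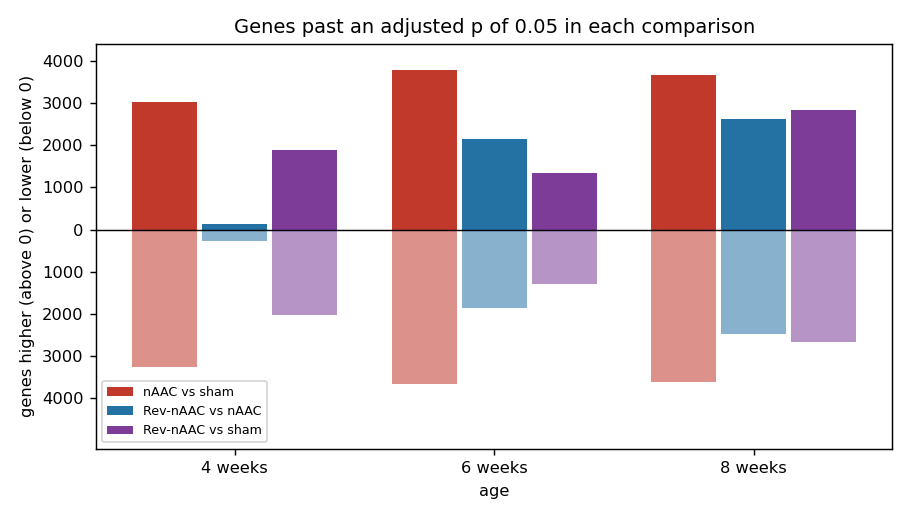
Bars give the number of genes past an adjusted p of 0.05 that were higher (above 0) or lower (below 0, lighter) in each comparison at 4, 6 and 8 weeks. nAAC differed from sham in 6283, 7453 and 7294 genes, and Rev-nAAC from nAAC in 394, 4002 and 5083.

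**Figure D4:**
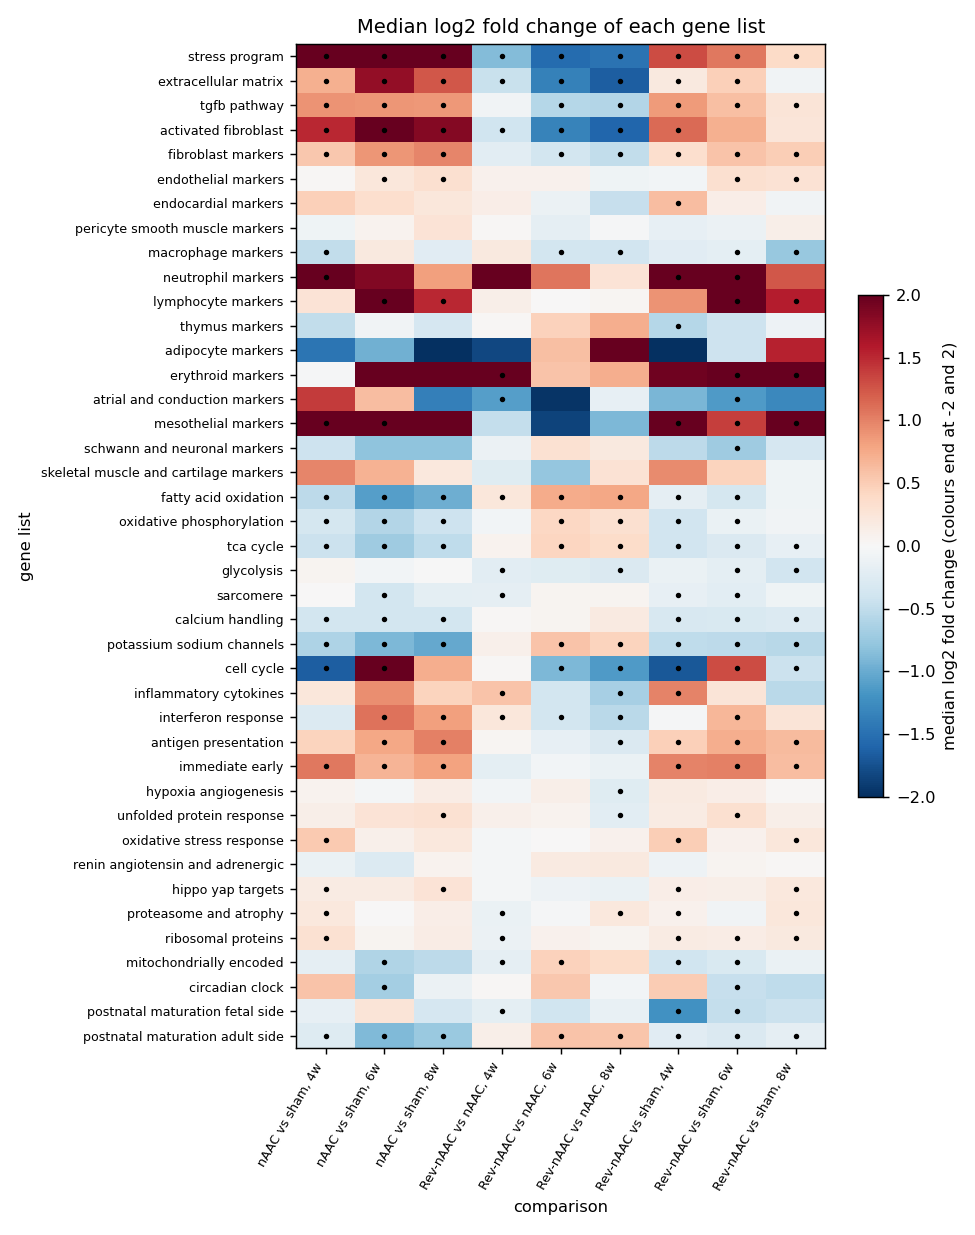
Median log2 fold change of each of the 41 gene lists (vertical) in the 9 comparisons (horizontal), from blue (lower) to red (higher), with a dot where the list passed an adjusted p of 0.05. The stress program list stands at 2.17, 2.76 and 2.28 in nAAC against sham and at -0.86, -1.54 and -1.47 in Rev-nAAC against nAAC.

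Rev-nAAC against nAAC asks how far hearts with the reversible constriction moved away from those with the lasting one. At 4 weeks Nppa averaged 2955 ± 1899 CPM in Rev-nAAC and 9559.5 ± 4147 in nAAC (SD, n = 5), a fall by 1.69 on the log2 scale (adjusted p = 0.033), and Myh7 fell by 1.76 (adjusted p = 0.046). The growth factor genes Ccn2 (-1.65 ± 0.38) and Tgfb2 (-0.87 ± 0.24) were lower. Among the panel, Nppb (-0.85), Ankrd1 (-0.88), Acta1 (-0.28), Postn (-1.58), Timp1 (-1.12), Myh6 (0.22), Atp2a2 (0.32), Col1a1 (-0.54), Col3a1 (-0.44), Fn1 (-0.41), Cpt1b (0.30) and Ppargc1a (0.20) did not pass. Lower in every Rev-nAAC library than in any nAAC library were Jchain (-2.06 ± 0.58), Cntn2 (-1.94 ± 0.35), Tent5b (-1.90 ± 0.46), Igfbp3 (-1.41 ± 0.29), Azin2 (-1.36 ± 0.31), Ncam1 (-1.02 ± 0.23) and Ptprn (-0.86 ± 0.18). Higher in every one were the monocyte chemokine Ccl2 (1.95 ± 0.47) and Ces1d (1.47 ± 0.32), Clec3b (1.05 ± 0.25), Tbx3 (1.04 ± 0.20), Lilrb4b (0.91 ± 0.22), Lilrb4a (0.84 ± 0.19), Tead4 (0.82 ± 0.20) and Zfp607a (0.79 ± 0.19), of which Lilrb4a and Lilrb4b are paralogs with uncertain values. The test found 394 genes, 122 higher and 272 lower, 38 and 62 of them at least 2-fold. That count was 1423 without nAAC replicate 1, 42 without nAAC replicate 3, 653, 194 and 146 without Rev-nAAC replicates 3, 4 and 5, and 971 without the 4 doubted libraries. Without nAAC replicate 3 Tbx3, Cntn2, Lilrb4a and Lilrb4b alone of these genes held their calls, and the others had adjusted p from 0.065 (Ces1d) to 0.22 (Tgfb2). Further single libraries, nAAC replicates 2, 4 and 5 and each Rev-nAAC replicate, ended calls of Jchain, Nppa, Myh7, Tgfb2, Tent5b, Azin2, Ccl2, Tead4 or Zfp607a, with adjusted p from 0.050 (Myh7) to 0.13 (Myh7). With only the compared groups in the fit none of these genes passed (adjusted p from 0.25 to 0.42), and with nAAC replicate 1 as sham Nppa and Myh7 had adjusted p = 0.20 and 0.29. In the male libraries Tbx3, Cntn2, Lilrb4a, Lilrb4b, Nppa, Ccl2, Jchain, Tead4 and Azin2 did not pass (adjusted p from 0.051 to 0.10). Without Rev-nAAC replicate 2 Myh7 had -2.55.

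Of the 24 stress program genes, 1 rose and 12 fell (1 and 18 adjusted over the list alone), downward with adjusted p = 2.3e-14, or adjusted p = 0.14 with an estimated correlation. Of the 23 glycolysis genes, 0 rose and 7 fell (1 and 10 adjusted over the list alone), downward with adjusted p = 9.4e-05, or adjusted p = 0.47 with an estimated correlation. The isomerase gene Gpi1 (-0.43 ± 0.09) was one of these. Of the 28 inflammatory cytokine genes, 3 rose and 0 fell (7 and 0 adjusted over the list alone), upward with adjusted p = 1.5e-04, or adjusted p = 0.47 with an estimated correlation. E-selectin, Sele (2.08 ± 0.45), was higher in Rev-nAAC, a call that ended without Rev-nAAC replicate 2 (adjusted p = 0.30). With only the compared groups in the fit Gpi1 and Sele had adjusted p = 0.42 and 0.44, and in the male libraries the inflammatory list had 0.20. Of the 15 atrial and conduction marker genes, 0 rose and 1 fell (0 and 2 adjusted over the list alone), downward with adjusted p = 0.0033, or adjusted p = 0.47 with an estimated correlation. Atrial myosin genes of this list, Myl7 (-4.85) and Myl4 (-3.26), were high in nAAC replicate 5 and did not pass. Of the 10 erythroid marker genes, 0 rose and 0 fell (7 and 0 adjusted over the list alone), upward with adjusted p = 0.029, or adjusted p = 0.85 with an estimated correlation. Of the 37 ribosomal protein genes, 0 rose and 0 fell (the same adjusted over the list alone), downward with adjusted p = 0.012, or adjusted p = 0.95 with an estimated correlation. The red cell transcripts were high in Rev-nAAC replicate 2. The erythroid call ended without nAAC replicates 1 or 4 or Rev-nAAC replicates 2 or 5 (adjusted p from 0.057 to 0.49). The ribosomal call ended without nAAC replicates 3 or 5 or Rev-nAAC replicates 1 or 3 (adjusted p from 0.051 to 0.89), with a median of 0.009 without nAAC replicate 5.

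At 6 weeks much of the load response was lower in Rev-nAAC than in nAAC hearts. Nppa averaged 1218 ± 854 against 11726 ± 2319 CPM, Myh7 416 ± 209 against 4466 ± 2516 and Postn 131 ± 76.9 against 945 ± 173 (SD, n = 5). The collagen and matrix genes fell together, with Col1a1 (-1.35 ± 0.28), Col3a1 (-1.29 ± 0.30), Fn1 (-1.22 ± 0.24), Tgfb2 (-1.74 ± 0.25), Ccn2 (-2.46 ± 0.39) and Timp1 (-2.65 ± 0.46), as did Nppb (-1.21 ± 0.38), Acta1 (-1.35 ± 0.46) and Ankrd1 (-1.44 ± 0.33). Higher were Myh6 (0.74 ± 0.17) and Atp2a2 (0.89 ± 0.14) (largest adjusted p = 0.028, Acta1). Values of Ppargc1a (0.64) and Cpt1b (0.28) did not pass. The largest rises were Lvrn (4.79 ± 0.82), Ano5 (4.71 ± 0.56), Inmt (4.20 ± 0.56), Ppl (4.14 ± 0.38), Clcn1 (3.83 ± 0.63), Ces1d (3.66 ± 0.34), Scn4b (3.46 ± 0.42) and Cngb3 (3.27 ± 0.55). The largest falls included Sprr1a (-5.75 ± 0.82), Chil1 (-4.40 ± 1.01), Nmrk2 (-4.25 ± 0.77), Serpinb1c (-3.69 ± 0.52), Tnfrsf11b (-3.66 ± 0.58) and Ereg (-3.52 ± 0.60). In total 4002 genes passed, 2136 higher and 1866 lower, 463 and 580 of them at least 2-fold, and 1069 in the male libraries, with 1 nAAC heart. The Acta1 call ended without Rev-nAAC replicates 1, 2 or 4 (adjusted p from 0.065 to 0.069), and the Nppb call without Rev-nAAC replicate 4 (adjusted p = 0.062). In the male libraries Nppb, Acta1, Ankrd1, Col1a1, Col3a1, Fn1, Postn, Myh6, Clcn1 and Tnfrsf11b kept their directions and did not pass (adjusted p from 0.052 to 0.52).

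Stress program genes, 24 in number, had 0 rises and 23 falls (the same adjusted over the list alone), downward with adjusted p = 1.6e-20, or adjusted p = 0.027 with an estimated correlation. Extracellular matrix genes, 45 in number, had 0 rises and 37 falls (0 and 39 adjusted over the list alone), downward with adjusted p = 1.0e-25, or adjusted p = 0.15 with an estimated correlation. TGF-beta pathway genes, 20 in number, had 1 rise and 11 falls (1 and 13 adjusted over the list alone), downward with adjusted p = 2.8e-05, or adjusted p = 0.24 with an estimated correlation. Examples were Col5a2 (-1.74 ± 0.26), Thbs1 (-2.42 ± 0.36) and Ltbp3 (-1.10 ± 0.15). Fatty acid oxidation genes, 33 in number, had 25 rises and 0 falls (27 and 0 adjusted over the list alone), upward with adjusted p = 3.8e-15, or adjusted p = 0.24 with an estimated correlation. Oxidative phosphorylation genes, 54 in number, had 47 rises and 0 falls (50 and 0 adjusted over the list alone), upward with adjusted p = 1.8e-17, or adjusted p = 0.44 with an estimated correlation. Hadh, Acaa2 and Cox7a1 were higher, at 1.11 ± 0.14, 1.38 ± 0.18 and 1.04 ± 0.15, in libraries whose mitochondrial share averaged 25.8% against 23.0% in nAAC.

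At 8 weeks scar transcripts were lower in Rev-nAAC than in nAAC. Postn averaged 84.1 ± 46.7 CPM against 1035 ± 146, Col1a1 70.6 ± 31.9 against 332 ± 63.4, and Nppa 1799.6 ± 987 against 11800.0 ± 1635 (SD, n = 5). Of the panel, Nppb (-2.55 ± 0.39), Myh7 (-2.48 ± 0.51), Ankrd1 (-1.69 ± 0.33), Col3a1 (-2.13 ± 0.31), Fn1 (-1.08 ± 0.24), Tgfb2 (-1.80 ± 0.24), Ccn2 (-1.91 ± 0.38) and Timp1 (-3.34 ± 0.48) fell and Myh6 (0.73 ± 0.17), Atp2a2 (0.91 ± 0.14) and Ppargc1a (1.22 ± 0.34) rose (largest adjusted p = 0.0049, Ppargc1a). The panel members Acta1 (-1.01) and Cpt1b (-0.09) did not pass. Gdf15 fell from 39.9 ± 17.3 to 2.78 ± 2.55 CPM, and other large falls included Sprr1a (-6.17 ± 0.80), Nmrk2 (-3.80 ± 0.75), Ptx4 (-3.73 ± 0.73), Atp6v0a4 (-3.72 ± 0.56) and Tubb3 (-3.72 ± 0.40). The methyltransferase gene Inmt rose from 1.43 ± 0.952 to 46.2 ± 17.5 CPM, with Chrna2 (4.36 ± 0.61), Acot1 (4.18 ± 0.56), Lvrn (3.82 ± 0.72), Ces1d (3.82 ± 0.35), Pbld1 (3.80 ± 0.50), Mme (3.21 ± 0.42) and Snai3 (3.11 ± 0.53) next. The comparison held 5083 genes, 2612 higher and the others lower, 573 and 761 of them at least 2-fold, and 596 in the male libraries, with 1 Rev-nAAC heart. There Postn, Col1a1, Col3a1, Fn1, Timp1, Nppa, Nppb, Ankrd1, Myh6, Gdf15, Nmrk2, Ptx4, Atp6v0a4, Chrna2 and Acot1 kept their directions and did not pass (adjusted p from 0.078 to 0.33). Ppargc1a had 0.23 in that fit (adjusted p = 0.87), and it stood at 164 and 211 CPM in Rev-nAAC replicates 2 and 4, both female, against 56.2 to 77.1 in the other 3.

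The stress program list held 0 rises and 19 falls among 24 genes (1 and 20 adjusted over the list alone), downward with adjusted p = 1.6e-14, or adjusted p = 0.15 with an estimated correlation. The extracellular matrix list held 1 rise and 38 falls among 45 genes (2 and 40 adjusted over the list alone), downward with adjusted p = 1.3e-21, or adjusted p = 0.24 with an estimated correlation. The inflammatory cytokine list held 0 rises and 12 falls among 28 genes (the same adjusted over the list alone), downward with adjusted p = 1.7e-04, or adjusted p = 0.42 with an estimated correlation. Interleukin 6 and the chemokines Ccl12 (-3.15 ± 0.49) and Ccl8 (-2.77 ± 0.73) fell, the former by 4.33, and in the male libraries the list had a median of -0.003 (adjusted p = 0.50). The macrophage marker list held 1 rise and 8 falls among 22 genes (the same adjusted over the list alone), downward with adjusted p = 0.0013, or adjusted p = 0.53 with an estimated correlation. The galectin Lgals3 (-3.42 ± 0.49) and the monocyte receptor Ccr2 (-1.62 ± 0.40) were among them, and the median turned to 0.45 in the male libraries (adjusted p = 0.18). The citric acid cycle list held 17 rises and 0 falls among 22 genes (18 and 0 adjusted over the list alone), upward with adjusted p = 3.3e-08, or adjusted p = 0.42 with an estimated correlation. The adipocyte marker list held 2 rises and 0 falls among 4 genes (2 and 1 adjusted over the list alone), not past the threshold with adjusted p = 0.81. Of the fat cell genes, Cfd was listed at 0 ± 0 CPM in nAAC and averaged 22.7 ± 50.8 in Rev-nAAC, and Car3 rose by 5.87 ± 1.63. Both were high in Rev-nAAC replicate 4, and the Cfd call ended without Rev-nAAC replicate 4 (adjusted p = 0.64) and the Car3 call without Rev-nAAC replicate 4 (adjusted p = 0.53), when Car3 turned to -1.61.

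Rev-nAAC against sham asks what remained different after a reversible constriction. At 4 weeks Nppa averaged 2955 ± 1899 CPM against 85.2 ± 25.7 in sham (SD, n = 5). Also higher were Myh7 (4.38 ± 0.56), Acta1 (3.15 ± 0.49), Ankrd1 (2.26 ± 0.34), Nppb (1.61 ± 0.38), Ccn2 (1.95 ± 0.38), Tgfb2 (1.54 ± 0.25), Timp1 (1.59 ± 0.47) and Postn (1.46 ± 0.47) (largest adjusted p = 0.019, Postn). Both Col3a1 (-0.94 ± 0.30) and Atp2a2 (-0.44 ± 0.14) were lower. Genes not past the test were Myh6 (-0.39), Col1a1 (0.17), Fn1 (0.03), Cpt1b (0.15) and Ppargc1a (-0.14). The potassium channel gene Kcnc1 and the lipocalin gene Lcn2 joined the largest rises, with Chil1 (6.42 ± 1.17), Tnmd (6.12 ± 0.99), Chodl (5.94 ± 0.93), Kcnc1 (5.42 ± 0.62), Lcn2 (5.05 ± 0.84) and Fam180a (4.97 ± 0.61) and Vgll2 at 6.93 ± 3.0 against 0.00609 ± 0.0136 CPM. Among the largest falls was Dbh, the enzyme that makes noradrenaline, with Aqp4 (-6.08 ± 0.54), Rgs7 (-4.73 ± 0.55), Drd2 (-3.78 ± 0.45), Lypd8l (-3.74 ± 0.47), Efemp1 (-3.38 ± 0.57), Pla2g5 (-3.27 ± 0.39), Dbh (-3.25 ± 0.38) and Tll2 (-2.83 ± 0.46). Here 3902 genes passed, 1886 higher and 2016 lower, 669 and 570 of them at least 2-fold. Calls ended for Col3a1 without Rev-nAAC replicates 2 or 4 (adjusted p from 0.051 to 0.068) and for Timp1 without Rev-nAAC replicate 2 (adjusted p = 0.059). They also ended for Postn without Rev-nAAC replicate 3 (adjusted p = 0.31) and for Atp2a2 without sham replicate 3 or Rev-nAAC replicates 2 or 3 (adjusted p from 0.054 to 0.077). With nAAC replicate 1 as sham, Nppa, Myh7, Postn, Fam180a and Atp2a2 had log2 values of 1.49, 0.40, 0.79, 1.62 and -0.37, with adjusted p = 0.20, 0.80, 0.28, 0.089 and 0.062. In the male libraries Atp2a2, Col3a1 and Timp1 had adjusted p = 0.16, 0.10 and 0.069. Myh7 stood at 3573 CPM in Rev-nAAC replicate 2 and at 594 to 1015 in the other 4, and without that library its log2 value was 3.61.

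Of the 24 stress program genes, 19 rose and 1 fell (21 and 1 adjusted over the list alone), upward with adjusted p = 1.8e-15, or adjusted p = 0.11 with an estimated correlation. Of the 36 cell cycle genes, 0 rose and 30 fell (0 and 32 adjusted over the list alone), downward with adjusted p = 1.8e-15, or adjusted p = 0.17 with an estimated correlation. Of the 54 oxidative phosphorylation genes, 0 rose and 43 fell (0 and 50 adjusted over the list alone), downward with adjusted p = 1.5e-15, or adjusted p = 0.33 with an estimated correlation. Of the 13 mitochondrially encoded genes, 0 rose and 8 fell (the same adjusted over the list alone), downward with adjusted p = 0.0038, or adjusted p = 0.39 with an estimated correlation. Of the 8 neutrophil marker genes, 7 rose and 0 fell (the same adjusted over the list alone), upward with adjusted p = 3.2e-04, or adjusted p = 0.31 with an estimated correlation. The granule genes S100a8 (5.52 ± 1.10), S100a9 (4.97 ± 1.03) and Lcn2 (5.05 ± 0.84) were highest in Rev-nAAC replicate 2. Of the 23 calcium handling genes, 0 rose and 8 fell (1 and 13 adjusted over the list alone), downward with adjusted p = 2.4e-04, or adjusted p = 0.17 with an estimated correlation. The sodium-calcium exchanger Slc8a1 (-0.66 ± 0.17) and the release channel Ryr2 (-0.80 ± 0.21) were lower.

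At 6 weeks natriuretic peptide transcripts were higher in Rev-nAAC than in sham hearts. Nppa averaged 1218 ± 854 against 137 ± 39.0 CPM (SD, n = 5). Higher too were Nppb (1.70 ± 0.38), Acta1 (2.85 ± 0.49), Ankrd1 (1.32 ± 0.33), Ccn2 (1.33 ± 0.37), Postn (1.38 ± 0.47) and Tgfb2 (0.72 ± 0.25) (largest adjusted p = 0.042, Tgfb2). The threshold was not reached by Myh7 (0.78), Myh6 (-0.40), Col1a1 (0.43), Col3a1 (0.34), Fn1 (0.44), Timp1 (0.10), Cpt1b (0.25) and Ppargc1a (-0.63). Atp2a2 was slightly lower, at -0.39 ± 0.14 with adjusted p = 0.049. The largest rises included those of the red cell genes Slc4a1 (5.07 ± 1.40), Hba-a2 (3.18 ± 0.78), Hbb-bt (3.12 ± 0.86) and Alas2 (3.11 ± 0.85), along with endothelin 3, Edn3 (3.39 ± 0.44), and the granule gene S100a9 (3.13 ± 1.01). The largest falls included Aqp4 (-3.08 ± 0.45), Cenpf (-2.66 ± 0.42), Ubxn10 (-2.27 ± 0.45), Ciart (-2.11 ± 0.42), Tlcd4 (-2.01 ± 0.26) and Drd2 (-1.91 ± 0.38), of which Ciart belongs to the circadian clock. The test passed 2634 genes, 1338 higher and 1296 lower, 469 and 196 of them at least 2-fold, and 4556 with voom. Without Rev-nAAC replicate 4, which held 0.452% of red cell counts, Slc4a1 and Hbb-bt had adjusted p = 0.11 and 0.054. Calls also ended for S100a9 without sham replicates 1, 4 or 5 or Rev-nAAC replicates 1 or 4 (adjusted p from 0.059 to 0.072). The Postn call ended without sham replicates 1, 2, 3, 4 or 5 or Rev-nAAC replicates 1, 2 or 3 (adjusted p from 0.054 to 0.14), and the Tgfb2 call without sham replicates 1, 2, 3 or 4 or Rev-nAAC replicates 1, 2 or 3 (adjusted p from 0.066 to 0.18). The Atp2a2 call ended without sham replicates 1, 2, 3, 4 or 5 or Rev-nAAC replicates 1, 2, 3 or 5 (adjusted p from 0.059 to 0.13). With sex as a covariate Slc4a1 had 3.23 (adjusted p = 0.057) and S100a9 2.27 (adjusted p = 0.098), and limma voom gave Slc4a1 3.18 (adjusted p = 0.061). With only the compared groups in the fit Ankrd1, Postn and Tgfb2 had adjusted p = 0.067, 0.063 and 0.052.

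Lymphocyte marker genes, 13 in number, had 9 rises and 0 falls (13 and 0 adjusted over the list alone), upward with adjusted p = 6.4e-08, or adjusted p = 0.17 with an estimated correlation. Erythroid marker genes, 10 in number, had 8 rises and 0 falls (9 and 0 adjusted over the list alone), upward with adjusted p = 5.4e-05, or adjusted p = 0.28 with an estimated correlation. Interferon response genes, 25 in number, had 13 rises and 0 falls (21 and 0 adjusted over the list alone), upward with adjusted p = 6.8e-09, or adjusted p = 0.28 with an estimated correlation. Cell cycle genes, 36 in number, had 20 rises and 1 fall (24 and 1 adjusted over the list alone), upward with adjusted p = 5.8e-09, or adjusted p = 0.28 with an estimated correlation. Ccnb1 and Cdc20 rose, by 4.14 ± 0.85 and 1.79 ± 0.35. Sarcomere genes, 24 in number, had 0 rises and 5 falls (0 and 7 adjusted over the list alone), downward with adjusted p = 0.0017, or adjusted p = 0.39 with an estimated correlation.

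At 8 weeks Rev-nAAC hearts had higher levels of some load-response genes than sham hearts. Nppa averaged 1799.6 ± 987 against 357 ± 282 CPM (SD, n = 5). Above sham were also Acta1 (1.45 ± 0.46), Ankrd1 (1.22 ± 0.33), Tgfb2 (1.08 ± 0.25) and Ccn2 (1.54 ± 0.38) (largest adjusted p = 0.013, Acta1). Below the threshold stayed Nppb (0.36), Myh7 (0.02), Postn (-0.47), Fn1 (0.14), Atp2a2 (-0.28), Cpt1b (-0.73) and Ppargc1a (0.22). Below sham in the fit of all libraries were Col1a1 (-1.05 ± 0.28), Col3a1 (-1.10 ± 0.30), Timp1 (-2.26 ± 0.47) and Myh6 (-0.43 ± 0.17) (largest adjusted p = 0.046, Myh6). The transferrin receptor gene Tfrc, which takes up iron, fell from 432 ± 75.9 to 40.3 ± 16.8 CPM. Other large falls included Tll2 (-5.58 ± 0.52), Pacsin1 (-5.20 ± 0.51), Aqp4 (-4.62 ± 0.51), Efemp1 (-3.73 ± 0.57), Cenpf (-3.55 ± 0.46) and Ccl7 (-3.39 ± 0.60). The largest rises included Vgll2 (6.57 ± 0.76), Chodl (6.49 ± 0.99), Kcnc1 (4.49 ± 0.55), Ankrd55 (4.07 ± 0.57), Il22ra1 (3.86 ± 0.46) and Fam180a (3.66 ± 0.53), with Xist at 277 ± 157 CPM in a group of 4 females and 1 male, against 0.0178 ± 0.0163 in sham. There were 5500 genes past the threshold, 2833 higher and 2667 lower, 708 and 555 of them at least 2-fold, and 1907 in the male libraries, with 1 Rev-nAAC heart. In those Col1a1, Col3a1, Timp1 and Myh6 had -0.20, -0.30, -1.52 and -0.48 (adjusted p = 0.79, 0.70, 0.21 and 0.32). The male Rev-nAAC library held 127 CPM of Col1a1, within the sham span of 108 to 203, and the 4 females 47.6 to 62.0. Nppa, Ankrd1, Tgfb2, Ccn2, Efemp1 and Ccl7 did not pass there either (adjusted p from 0.082 to 0.34). The Myh6 call ended without sham replicates 1, 2 or 5 or Rev-nAAC replicates 1, 3, 4 or 5 (adjusted p from 0.065 to 0.10), and the Acta1 call without Rev-nAAC replicate 5 (adjusted p = 0.079). Without sham replicate 3, at 840 CPM, Nppa had a log2 value of 2.93 in place of 2.33. The Xist call ended in limma voom with quality weights (adjusted p = 0.34).

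The macrophage marker list held 1 rise and 15 falls among 22 genes (2 and 16 adjusted over the list alone), downward with adjusted p = 1.8e-05, or adjusted p = 0.55 with an estimated correlation. Integrin and mannose receptor genes were among them, with Itgam (-2.03 ± 0.24), Mrc1 (-1.48 ± 0.20) and Cd68 (-1.43 ± 0.26), and the list had adjusted p = 0.15 in the male libraries. The glycolysis list held 3 rises and 16 falls among 23 genes (the same adjusted over the list alone), downward with adjusted p = 3.7e-04, or adjusted p = 0.56 with an estimated correlation. The endothelial marker list held 8 rises and 0 falls among 18 genes (the same adjusted over the list alone), upward with adjusted p = 0.0087, or adjusted p = 0.62 with an estimated correlation. The fibroblast marker list held 7 rises and 1 fall among 16 genes (8 and 2 adjusted over the list alone), upward with adjusted p = 0.014, or adjusted p = 0.65 with an estimated correlation. This call ended without Rev-nAAC replicate 5 (adjusted p = 0.13). The proteasome and atrophy list held 13 rises and 1 fall among 23 genes (14 and 1 adjusted over the list alone), upward with adjusted p = 2.6e-04, or adjusted p = 0.55 with an estimated correlation. The autophagy receptor Sqstm1 (1.20 ± 0.11) and the cathepsin Ctsl (1.19 ± 0.12) were higher.

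The share of the nAAC change absent from Rev-nAAC hearts was measured over 20 splits. Genes were called and read in separate nAAC and sham libraries. It was 25.3 ± 7.39% at 4 weeks (SD over splits), 56.3 ± 1.70% at 6 weeks and 45.8 ± 4.09% at 8 weeks. Single Rev-nAAC libraries averaged 25.5 ± 12.7%, 56.3 ± 21.7% and 45.1 ± 4.54% (SD, n = 5). The share was higher at 8 than at 4 weeks by 19.5 (exact permutation test, two-sided, p = 0.016, adjusted p = 0.024, n = 5) and at 6 than at 4 weeks by 30.8 (exact permutation test, p = 0.016, adjusted p = 0.024, n = 5), whereas 8 and 6 weeks differed by -11.2 (exact permutation test, p = 0.32, n = 5). Rev-nAAC 6-week replicate 4 stood at 93.7%, and the 6-week share was 47.0% without it. On an axis from sham (0) to nAAC (100), the sham groups averaged 2.88 ± 5.41, 2.91 ± 2.01 and 3.27 ± 14.1, and the Rev-nAAC groups 73.9 ± 11.3, 43.7 ± 19 and 49.4 ± 3.67 at 4, 6 and 8 weeks. Library nAAC 4-week replicate 1 had a position of 73.3, below the mean of 93.7 ± 17.8 of its group.

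**Figure D5:**
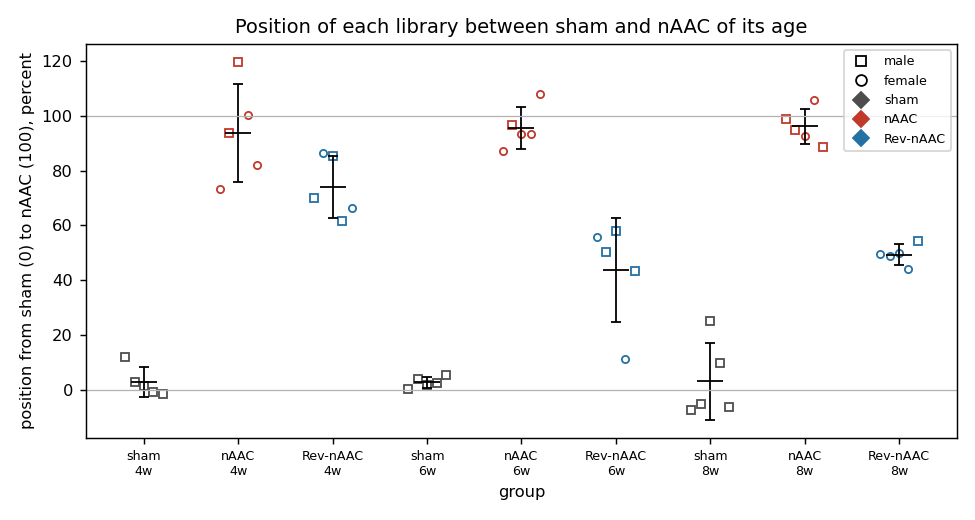
Position of each library between the sham mean (0) and the nAAC mean (100) of its age, in percent, by group, with the mean and SD in black, colour for the operation and shape for the sex. The Rev-nAAC groups average 73.9, 43.7 and 49.4 at 4, 6 and 8 weeks, and Rev-nAAC 6-week replicate 4 lies at 11.2.

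Genes that differed between nAAC and sham were also counted by how they moved in Rev-nAAC. At 4 weeks 344 of 6283 (5.48%) moved back towards sham past the test, at 6 weeks 3472 of 7453 (46.6%) and at 8 weeks 3125 of 7294 (42.8%). Independent calls would give 78.9, 965 and 1200. Simulation with no difference gave 0, which leaves out the effects, and separate nAAC libraries for both sides gave 213 of 4678, 2264 of 5581 and 1978 of 5204. Still different from sham in the same direction were 3354 (53.4%), 2266 (30.4%) and 3508 (48.1%) genes, against 795, 636 and 1299 for independent calls, 0 in that simulation, and 2008 of 3939, 1125 of 5350 and 2275 of 5097 with separate sham libraries. The correlation of both differences was -0.54, -0.80 and -0.66 for moving back (simulated -0.50 to -0.48). It was 0.88, 0.77 and 0.66 for remaining (simulated 0.50 to 0.52). At 4 weeks -0.54 is near what shared libraries alone give. Opposite to the nAAC change and past the test against sham were 0, 10 and 121 genes in Rev-nAAC.

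Sham hearts at 8 and 4 weeks were compared to show the change with age in hearts without a constriction. Cyclin B1, Ccnb1, went from 5.11 ± 0.853 to 0.165 ± 0.113 CPM (SD, n = 5), and Depdc1a (-5.29 ± 0.83), Pimreg (-4.86 ± 0.74), Hmmr (-4.79 ± 0.66) and Mxd3 (-4.76 ± 0.77) were the other largest falls. Myh7 rose from 63.9 ± 5.01 to 774 ± 515 CPM. Rises were also found for Nmrk2 (3.61 ± 0.81), Pacsin1 (3.26 ± 0.44), Ptgds (3.09 ± 0.34), Nppa (2.07 ± 0.45) and Timp1 (2.06 ± 0.47) (largest adjusted p = 0.0013, Timp1), while Col3a1 (-1.29 ± 0.30) and Fn1 (-0.74 ± 0.24) fell. Not past the test were Nppb (-0.08), Myh6 (0.30), Acta1 (1.04), Ankrd1 (0.52), Atp2a2 (0.16), Col1a1 (-0.34), Postn (0.23), Tgfb2 (0.25), Ccn2 (0.66), Cpt1b (0.71) and Ppargc1a (0.05). The count was 3506 genes, 1658 higher and 1848 lower at 8 weeks, 203 and 566 of them at least 2-fold, with 5391 in a fit of these groups alone and 6324 with voom. Without sham 8-week replicate 3, at 840 CPM, Nppa had 1.47, and Timp1 stood at 10.6 and 14.8 CPM in 8-week replicates 3 and 4 against 2.98 to 3.75 in the other 3. The Fn1 call ended without sham 4-week replicate 4 or sham 8-week replicates 1, 2 or 5 (adjusted p from 0.059 to 0.074). With nAAC 4-week replicate 1 as sham, Nppa and Myh7 had log2 values of -1.56 and -0.38 here, and Myh7 had 0.45 in the nAAC interaction.

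Interactions tested whether an effect differed between 8 and 4 weeks. For nAAC against sham the mitotic genes Hmmr (4.40 ± 0.86), Depdc1a (4.36 ± 1.10), Nek2 (4.07 ± 0.81) and Ccnb1 (4.06 ± 0.78) and the protease Adamts4 (4.32 ± 0.72) had a more positive effect at 8 weeks. The effect was more negative at 8 weeks for Chad (-4.19 ± 1.36), Myh7 (-3.64 ± 0.71), Sbk3 (-3.54 ± 0.81) and Jchain (-3.50 ± 0.97). In this test 2094 genes passed, 1059 of them more positive and 1035 more negative, and 3599 with voom. The Chad call ended without sham 4-week replicates 2, 3, 4 or 5, sham 8-week replicates 2 or 3, nAAC 4-week replicate 2 or nAAC 8-week replicates 1, 2 or 4 (adjusted p from 0.057 to 0.076). The Jchain call ended without sham 8-week replicate 3 (adjusted p = 0.066), and with nAAC 4-week replicate 1 as sham Jchain had -2.02 (adjusted p = 0.18). For Rev-nAAC against nAAC the chemokines Ccl7 (-3.76 ± 0.80), Ccl12 (-3.75 ± 0.64) and Ccl2 (-3.39 ± 0.68), E-selectin, Sele (-4.0 ± 0.65), and Slfn4 (-3.42 ± 0.95) had a more negative effect at 8 weeks. It was more positive for Sbk3 (3.59 ± 0.84), Snai3 (3.01 ± 0.72), Car3 (9.24 ± 2.51) and Cyp2e1 (9.19 ± 1.99), among 1222 genes, 626 up and 596 down. Without Rev-nAAC 8-week replicate 4 Car3 and Cyp2e1 had adjusted p = 0.72 and 0.37 and the count was 552. It was 474 and 2458 without Rev-nAAC 4-week replicate 3 and Rev-nAAC 8-week replicate 5, 747 without Rev-nAAC 8-week replicate 2 and 793 without nAAC 8-week replicate 4. Car3 also lost its call without nAAC 4-week replicate 5 (adjusted p = 0.060), and Slfn4 without nAAC 8-week replicate 4 or Rev-nAAC 4-week replicate 2 (adjusted p = 0.096 and 0.14). With only the compared groups in the fit no gene passed, and Ccl7, Ccl12, Ccl2, Sele, Slfn4, Sbk3, Snai3 and Cyp2e1 had adjusted p from 0.067 to 0.16. In the male libraries neither these nor Car3 passed (adjusted p from 0.20 to 0.94), with Ccl7 at -1.53 and Ccl2 at -1.32, and the count was 5. For Rev-nAAC against sham Pacsin1 (-5.57 ± 0.69), Nmrk2 (-5.51 ± 1.07), Chil1 (-5.42 ± 1.49), Lcn2 (-4.44 ± 1.07) and Myh7 (-4.36 ± 0.71) had a more negative effect. A more positive one was found for Fam124b (4.57 ± 0.84), Cd247 (3.34 ± 0.57), Npas2 (3.30 ± 0.62) and Car3 (9.19 ± 2.30), among 1576 genes, 742 up and 834 down (3636 with voom and 312 in the male libraries). Without Rev-nAAC 4-week replicate 2 Chil1 and Lcn2 had adjusted p = 0.11 and 0.086, without Rev-nAAC 8-week replicate 4 Car3 had 0.72, and without sham 4-week replicate 1 it had 0.15. With nAAC 4-week replicate 1 as sham Myh7 had -0.38 and Chil1 -2.91 (adjusted p = 0.89 and 0.16). In the male libraries Nmrk2, Chil1, Lcn2, Fam124b, Cd247, Npas2 and Car3 did not pass (adjusted p from 0.063 to 0.75), with Cd247 at 1.97, Npas2 at 1.24 and Car3 at 3.38. Cfd passed both Rev-nAAC contrasts but was listed at 0 counts in nAAC at 8 weeks, and without Rev-nAAC 8-week replicate 4 it had adjusted p = 0.39 against nAAC and 0.93 against sham, where it also had 0.40 without sham 4-week replicate 1.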

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

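The tests of sex, cell share and a mislabelled library were chosen only after their results were seen. At 4, 6 and 8 weeks 6283, 7453 and 7294 genes differed between nAAC and sham, in animals that differed also in sex. Genes called with female nAAC libraries had a median difference from sham in male nAAC libraries of 112% and 89.7% of that in the females at 4 and 8 weeks. At 6 weeks, with 1 male nAAC library, the count with sex as a covariate was 93.6% of that without it, which argues, like the medians, against sex as the whole cause. Fewer cardiomyocytes alone would raise other cell markers alike. Of 4 cell lists the top, fibroblast, lay above the lowest, macrophage, by 1.04 ± 0.164, 1.27 ± 0.106 and 1.35 ± 0.164 in log2 (SE). That argues against this cause alone. Load and shifts of cell types stay open.

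Rev-nAAC differed from sham in 5500 genes at 8 weeks and in 2634 at 6 weeks (7406 and 4556 with voom quality weights, and 3400 at 6 weeks without replicate 4). The covariance of differences was 1.74 times as large at 8 weeks (0.330 ± 0.0172 against 0.190 ± 0.0146, SD over 100 splits). The splits reuse the same libraries, so a wider spread at 6 weeks stays open. Sex, with 4 females at 8 weeks and 2 at 6 weeks, cannot be told apart. With sex as a covariate the ratio of the counts was 1.73, but 1.33 without Rev-nAAC 6-week replicate 4, and 1 male is left at 8 weeks. Age stays open as the biological explanation.

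Only 394 genes differed between Rev-nAAC and nAAC at 4 weeks, from 42 without nAAC replicate 3 to 1423 without nAAC replicate 1. The recovered share was 25.3%, against 56.3% at 6 weeks and 45.8% at 8 weeks, from 2398, 5732.5 and 5971 genes. Splits reuse the same libraries, so as large a recovery, hidden by spread, stays open. That nAAC 4-week replicate 1 is a sham heart, as its treatment tag says, is argued against by its position of 73.3, against 2.88 ± 5.41 in sham (SD, n = 5). A shift of 4-week sham that lowers the share, or a shorter time since release, stays open and was not tested.

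Other splits of the same libraries were counted for each result, with the real split among the 100. For nAAC against sham only the real split reached its count, with 6283, 7453 and 7294 genes against at most 4061, 2716 and 3907 in other splits at 4, 6 and 8 weeks. The same held for Rev-nAAC against sham, with 3902, 2634 and 5500 genes against 600, 1547 and 3494. It held for Rev-nAAC against nAAC at 6 and 8 weeks, with 4002 and 5083 against 1487 and 3065. At 4 weeks, however, 18 of 100 splits reached 394 genes, so chance is not excluded. There the highest other split gave 2151 genes, and what set that split apart was not tested. Only the real split reached the count for sham at 8 against 4 weeks (3506 genes against 719) and for the 3 interactions (2094 against 1962, 1222 against 631, 1576 against 1311). Another split gave more gene lists in each comparison of operations, so chance is not excluded. Rev-nAAC against sham had 26, 29 and 20 lists at 4, 6 and 8 weeks, reached by 4, 2 and 17 splits. The highest others were 27, 30 and 25. Rev-nAAC against nAAC had 14, 14 and 19, reached by 47, 57 and 4 (highest others 26, 23 and 21). nAAC against sham had 20, 21 and 18, reached by 7, 17 and 46 (21, 24 and 24).

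Of 210 groups of 5 values, 19 held a library far from the other 4, where chance gives about 10.5. Rev-nAAC 6-week replicate 4 had a red cell share of 0.452%, with Atp2a2 at 11485, Ppargc1a at 109 and Col1a1 at 62.8 CPM. Rev-nAAC 4-week replicate 3 had Col1a1 at 402, Postn at 750.0 and Ccn2 at 482 CPM. Rev-nAAC 8-week replicate 5 had Col1a1 at 127, Postn at 167 and Nppb at 452 CPM. Sham 4-week replicate 1 had Nppa at 129.85 and Acta1 at 616 CPM, and sham 4-week replicate 3 had Nppb at 283 CPM. Sham 6-week replicate 1 had Myh6 at 22743 and Atp2a2 at 13489 CPM. Myh7 stood at 3573 CPM in Rev-nAAC 4-week replicate 2 and Myh6 at 5753 CPM in nAAC 4-week replicate 3. Fn1 stood at 289.8 CPM in nAAC 6-week replicate 3 and Timp1 at 23.7 CPM in nAAC 6-week replicate 4.

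Effects differed between 8 and 4 weeks in 2094 genes for nAAC against sham, 1222 for Rev-nAAC against nAAC and 1576 for Rev-nAAC against sham. The largest of the first kind, in log2 and partly through sham, included Hmmr 4.40, Depdc1a 4.36, Adamts4 4.32, Nek2 4.07, Ccnb1 4.06, Chad -4.19, Myh7 -3.64, Sbk3 -3.54 and Jchain -3.50. Against nAAC they were Cfd 17.88, Car3 9.24, Cyp2e1 9.19, Sbk3 3.59, Snai3 3.01, Sele -4.0, Ccl7 -3.76, Ccl12 -3.75, Slfn4 -3.42 and Ccl2 -3.39. For Rev-nAAC against sham they were Cfd 10.60, Car3 9.19, Fam124b 4.57, Cd247 3.34, Npas2 3.30, Pacsin1 -5.57, Nmrk2 -5.51, Chil1 -5.42, Lcn2 -4.44 and Myh7 -4.36. Without Rev-nAAC 8-week replicate 4 Cfd, Car3 and Cyp2e1 had adjusted p = 0.39, 0.72 and 0.37 against nAAC, Cfd and Car3 had 0.93 and 0.72 against sham, and the 1222 genes were 552. Without Rev-nAAC 4-week replicate 2 Chil1, Lcn2 and Slfn4 had adjusted p = 0.11, 0.086 and 0.14. Without nAAC 8-week replicate 4 Slfn4 had adjusted p = 0.096, without sham 8-week replicate 3 Jchain had 0.066, and without nAAC 4-week replicate 5 Car3 had 0.060 against nAAC. Without sham 4-week replicate 1 Cfd and Car3 had adjusted p = 0.40 and 0.15 against sham, and the Chad call ended without any of 10 libraries, with adjusted p from 0.057 to 0.076. The fitted values of Cfd are no bounds, since nAAC at 8 weeks is listed at 0. The recovered share was higher at 8 than at 4 weeks by 19.5 and at 6 than at 4 weeks by 30.8 percentage points (exact permutation test, two-sided, p = 0.016 for each).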

How the results depend on the processing

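The fits of male libraries, those without the 4 doubted libraries and the share without the sex term were tests chosen only after the data were seen. Of the 1662 results for named genes, RLE normalization left 1656 with the same direction and side of the threshold, DESeq2 1603, the replicate block 1630 and sex as a covariate 1597. No filter left 1608, the fit without the doubted libraries 1575, voom 1555, only the compared groups 1465 and the male libraries 1267. DESeq2 and the fit of the compared groups gave no value for some of these genes. Of 369 list results, RLE left 362, the replicate block 365, sex as a covariate 348, no filter 343, only the compared groups 339, the male libraries 308, fry 294 and an estimated correlation 190. Low counts limit the genes with few reads, and the number of male libraries limits the male fits, which hold 1 nAAC heart at 6 weeks and 1 Rev-nAAC heart at 8 weeks, assumed to vary like the other groups.

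The count of 394 genes for Rev-nAAC against nAAC at 4 weeks became 242 with no filter, 749 in male libraries, 971 without the doubted libraries, 1215 with the conflicting library as sham, 670 with DESeq2 and 710 with voom. With only the compared groups in the edgeR fit it was 0, with 1174 genes at an unadjusted p under 0.05. The interaction of Rev-nAAC against nAAC, 1222 genes, became 718 with no filter, 519 with sex as a covariate, 5 in male libraries and 127 without the doubted libraries. With only the compared groups it was 0 in edgeR, with 2788 genes at an unadjusted p under 0.05, while DESeq2 gave 1589 and voom 1824. Male libraries gave 4500 genes for nAAC against sham at 6 weeks, 1069 and 596 for Rev-nAAC against nAAC at 6 and 8 weeks, 1907 for Rev-nAAC against sham at 8 weeks and 312 for its interaction, in fits of fewer samples. Sham at 8 against 4 weeks gave 5391 genes with only the compared groups and 6324 with voom. Voom also gave 4556 genes for Rev-nAAC against sham at 6 weeks, 3599 for the nAAC interaction and 3636 for that of Rev-nAAC against sham. An estimated correlation left 1, 0 and 0 lists for nAAC against sham at 4, 6 and 8 weeks, 0, 1 and 0 for Rev-nAAC against nAAC, and 0, 0 and 0 for Rev-nAAC against sham. Unadjusted, camera then gave 4, 7 and 5, 2, 8 and 5, and 9, 7 and 2 lists, and fry gave 27, 28 and 30, 1, 16 and 19, and 24, 26 and 23 past the threshold. Where neither fewer samples nor fewer genes explain a change, the cause was not tested.

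With each library left out in turn, nAAC against sham gave from 5227 to 6832 genes at 4 weeks, from 6948 to 7194 at 6 weeks and from 6601 to 7251 at 8 weeks. Rev-nAAC against nAAC gave from 42 (without nAAC 4-week replicate 3) to 1423 (without nAAC 4-week replicate 1) at 4 weeks, and 653, 194 and 146 without Rev-nAAC 4-week replicates 3, 4 and 5. It gave from 2795 to 4020 at 6 weeks and from 4140 to 5747 at 8 weeks. Rev-nAAC against sham gave from 3138 to 3829, from 1812 to 3400 and from 4857 to 5919. Sham at 8 against 4 weeks gave from 2840 to 3481. The interactions gave from 1514 to 2334, from 474 (without Rev-nAAC 4-week replicate 3) to 2458 (without Rev-nAAC 8-week replicate 5) and from 1264 to 2332, and the second gave 793, 747 and 552 without nAAC 8-week replicate 4 and Rev-nAAC 8-week replicates 2 and 4. Lists numbered from 18 to 22, 18 to 21 and 18 to 21 for nAAC against sham, 13 to 18, 11 to 14 and 16 to 19 for Rev-nAAC against nAAC, and 20 to 28, 27 to 30 and 16 to 22 for Rev-nAAC against sham. Without each Rev-nAAC library the recovered share ran from 21.6 to 29.6% at 4 weeks, 47.0 to 60.8% at 6 weeks and 44.7 to 47.2% at 8 weeks. Over the splits of the nAAC and sham libraries it ran from 12.9 to 35.8%, 52.5 to 58.6% and 39.2 to 56.1%, and with the sex term removed it was 25, 55.9 and 41.9%. Of 1349 called gene results 171 lost their call without some library, and of 181 list calls 39.

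Directions turned in these cases among others. With no filter the mesothelial list had -1.01 in Rev-nAAC against sham at 8 weeks. In male libraries Rev-nAAC against sham at 4 weeks gave Slc4a1 -0.22 and Bpgm -0.02, and Rev-nAAC against nAAC at 6 weeks Cxcl1 -0.38. In male libraries at 8 weeks Rev-nAAC against nAAC gave Tox -0.57, Car3 -0.74, Ddit3 0.09, Ctsl -0.051, Dbp 0.071, Bmal1 -0.15 and Npas2 -1.26, and against sham Ms4a1 -1.17, Cd79a -0.41, Cfd -7.65, Acot1 -0.61, Aldh18a1 0.074 and Amotl2 -0.22. List medians in male libraries were -0.14 for erythroid genes in Rev-nAAC against nAAC at 4 weeks. At 8 weeks they were -0.17 for fibroblast, 0.45 for macrophage, 0.19 for cell cycle, 0.12 for antigen presentation and 0.31 for unfolded protein genes (adjusted p = 3.9e-04 for the last), and 0.40 for cell cycle against sham. Without the doubted libraries Car3 had -1.60 against nAAC and Cfd -4.89 against sham at 8 weeks, and without Rev-nAAC 8-week replicate 4 alone -1.61 and -4.90. With the conflicting library as sham, Myh7 had -0.38 and Nppa -1.56 in sham at 8 against 4 weeks, and Myh7 0.45 in the nAAC interaction. With voom Car3 had -1.05 against nAAC and Cfd -3.03 against sham at 8 weeks, and in the interaction against sham -0.75 and -0.57. With each library left out, Car3 against nAAC ran from -1.61 to 6.19 and Cfd against sham from -4.90 to 5.37 at 8 weeks. The ribosomal list in Rev-nAAC against nAAC at 4 weeks ran from -0.20 to 0.009, the highest without nAAC 4-week replicate 5. The cause of these turns was not tested.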

Other observations

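All tests of gene lists here were fixed before their results were seen, while the age shown for each list was picked afterwards. Epithelial keratins of the mesothelial list were higher in nAAC than in sham at 4 weeks, with Krt8 (6.75 ± 0.64) and Krt18 (6.02 ± 0.62) (SE, n = 5). The list result was mesothelial marker (2 rose and 0 fell of 4, 2 and 0 adjusted over the list alone, adjusted p = 0.0067 upward, or adjusted p = 0.24 with an estimated correlation). In Rev-nAAC hearts at 8 weeks both were still above sham, with Krt8 (4.38 ± 0.55) and Krt18 (3.49 ± 0.57). Genes of cardiac nerves moved apart in nAAC against sham at 8 weeks, with the noradrenaline enzyme Dbh (-2.80 ± 0.38) lower and the neuronal tubulin Tubb3 (1.30 ± 0.34) higher. Their list had this result: schwann and neuronal marker (3 rose and 5 fell of 10, 3 and 5 adjusted over the list alone, adjusted p = 0.36). Single genes of the renin-angiotensin and adrenergic list went both ways, with Adra1b (-2.55 ± 0.26), Adrb1 (-1.52 ± 0.18) and Agtr1a (-1.58 ± 0.22) lower and the receptor kinase Grk5 (1.30 ± 0.13) higher. That list did not pass: renin-angiotensin and adrenergic (7 rose and 8 fell of 19, 7 and 8 adjusted over the list alone, adjusted p = 0.71, median 0.08, mean -0.41, test downward). The vessel-stabilizing factor Angpt1 (-2.75 ± 0.30) fell, within the list hypoxia and angiogenesis (9 rose and 5 fell of 20, 9 and 5 adjusted over the list alone, adjusted p = 0.27). The endocardial, pericyte and smooth muscle, thymus, and skeletal muscle and cartilage lists did not pass here (adjusted p from 0.16 to 0.77).

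Some Hippo pathway targets were higher in Rev-nAAC than in sham at 4 weeks, with the list result Hippo and YAP target (6 rose and 0 fell of 13, 6 and 0 adjusted over the list alone, adjusted p = 0.013 upward, or adjusted p = 0.23 with an estimated correlation). Some fetal genes were lower in Rev-nAAC than in sham at 6 weeks, as in fetal-side maturation (0 rose and 5 fell of 14, 0 and 7 adjusted over the list alone, adjusted p = 0.0012 downward, or adjusted p = 0.17 with an estimated correlation), and insulin-like growth factor 2, Igf2 (-1.11 ± 0.23), was one of them. Igf2 and the imprinted genes H19 and Plagl1 also fell in nAAC against sham at 8 weeks, with Igf2 (-1.91 ± 0.23), H19 (-2.58 ± 0.36) and Plagl1 (-2.39 ± 0.33). Clock genes in opposite phase moved in opposite directions in Rev-nAAC against sham at 8 weeks, with Bmal1 (2.25 ± 0.47) higher and Dbp (-2.35 ± 0.51) lower. The clock list result was circadian clock (3 rose and 6 fell of 16, 3 and 7 adjusted over the list alone, adjusted p = 0.40), and the hour at which hearts were taken is not in the labels.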
